A study of Mus musculus with 4 samples.

How the data were processed

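RNA was sequenced from back skin of male BALB/c mice aged 8 to 9 weeks that received 5% imiquimod (IMQ) cream, 47 mg per day, on days 1 to 5. Imiquimod is a ligand of Toll-like receptor 7 that gives a psoriasis-like dermatitis when it is put on mouse skin. About 1 h after the cream, skin received either a lotion without the compound (IMQ+VEH) or the lotion with IDMF (IMQ+IDMF), isosorbide di-(methyl fumarate), a pro-drug of dimethyl fumarate. Skin was collected on day 6. Groups were taken from the sample labels. There was 1 IMQ library, 2 IMQ+VEH libraries (replicates 1 and 2) and 1 IMQ+IDMF library. Libraries were read in single-end runs of 50 cycles.

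For each library the authors deposited one table with 20611 gene symbols, a raw count per gene (counts) and an FPKM value per gene (fragments per kilobase of transcript, scaled to library size), as named in the file headers. The submitters' processing notes name TopHat2, Cufflinks and HTSeq and the builds GRCm38 and mm10. Versions, the annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads of near-identical family members (Sprr2, Lce3, Stfa, Defb and hair keratin genes) and of genes whose exons overlap on opposite strands may therefore be assigned to a relative or a neighbour. Gene positions and exon overlaps were looked up in the GENCODE M21 annotation of GRCm38, which held 276 of the 278 genes looked up by symbol.

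Tests used the counts. The fit was made with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, filterByExpr by group, TMM library sizes, 1 mean per group). The filter asked for a count of about 10 in at least 1 library and a total of 15, and left 15068 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. Only the IMQ+VEH pair is replicated, so the fit had 1 residual degree of freedom per gene, shared across genes with 11.2 prior degrees of freedom. The single IMQ and IMQ+IDMF libraries were assumed to vary like the IMQ+VEH pair. The common biological coefficient of variation was 24%. The labels call the libraries independent biological replicates. The sequencing core's sample number of IMQ+VEH replicate 2 lies apart from those of the other 3 libraries. Whether it was prepared in another batch is not given in the sources used here, and a batch could not be separated from the spread of the IMQ+VEH pair, on which the main tests rest. No paired comparison was possible, because only IMQ+VEH has 2 replicates. Standard errors (SE) of log2 fold changes were the fold change divided by the square root of its F statistic. IMQ+IDMF against IMQ is 1 library against 1, so only sizes are given. A secondary fit compared IMQ+IDMF with the 3 other libraries as 1 group (2 residual degrees of freedom).

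Lists of genes were fixed before the data were examined: 15 pathways and 15 cell types. They are named with their results in the report. Of these 30 lists, 29 had at least 5 tested members. The red blood cell list had 2 and was not tested. Lists were tested with camera (limma 3.58.1, two-sided) at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The last 2 rest on the 1 residual degree of freedom from the IMQ+VEH pair and had little power. A list that they did not call is therefore not shown to be unchanged. The preset correlation is an assumption. These libraries could not measure it well, but the IMQ+VEH pair spoke against it for many lists, as given in the results. Each list is also described by the median over its members of the log2 CPM difference (prior count 2) between libraries. The percentile of that median among 10000 random lists of the same size and similar expression was taken too. It is given mostly as the number of lists outside the central 95%.

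Named genes followed a rule fixed before the data were examined. Genes needed a mean log2 CPM of at least 1, and predicted, Rik, antisense and pseudogene names were left out. The 12 genes with IMQ+IDMF farthest above all 3 other libraries, and the 12 farthest below, were named by their smallest difference to any of the 3. For IMQ+VEH against IMQ, the 6 highest and the 6 lowest were named in the same way, with genes past the threshold first. For each list, up to 4 members with the largest smallest difference in the direction of the list's median were taken. Nqo1, Hmox1, Gclc, Srxn1, Il17a, Il17f, Il22, Il23a, Il1b, S100a8, S100a9, Krt6a, Krt16 and Hcar2 were named whatever their values. Other genes are marked as chosen after their values were seen. A gene that the rule names for IMQ+VEH against IMQ is not reported here.

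Alternatives were DESeq2 1.42.0 with its own size factors and filter, DESeq2 size factors or total counts in edgeR, no filter, a mean count of at least 50, a robust fit, a fit without muscle, adipocyte and hair follicle genes, IMQ and IMQ+VEH as 1 group, leaving out libraries in turn, and lists without shared members. Chosen after the data were seen were fits on only the 3 libraries of both groups, list medians from log2(FPKM + 1), and other scalings and left-out libraries for IMQ+VEH against IMQ. Figures were drawn with matplotlib 3.10.9.

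The fit was tested on simulated data with the same depths, with 200 changed genes in each of 3 runs. Each gene was given the trend of spread at its expression and no spread of its own, unlike the real genes. Changed genes were taken only from those above a minimum mean expression. The shares recovered may therefore be higher than in the real data. For IMQ+IDMF against IMQ+VEH it recovered 22.7% of genes changed 2-fold, 86.0% at 4-fold and 95.3% at 8-fold. For IMQ+VEH against IMQ it recovered 20.7%, 82.7% and 99.3%. Calls of unchanged genes over the 3 runs were 23 and 24.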

Results

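The data were read counts from 4 libraries of imiquimod-treated mouse back skin: 1 with imiquimod alone (IMQ), 2 that also received the lotion without the compound (IMQ+VEH) and 1 that also received the lotion with IDMF (IMQ+IDMF). Total counts were 26337985 for IMQ, 26639628 and 21167149 for IMQ+VEH replicates 1 and 2, and 21991604 for IMQ+IDMF. Counts were found for 16016 to 16648 genes per library. The 10 most abundant genes took 8.06% to 10.1% of the counts. A count of 3, taken as the floor for a gene not detected, equals 0.107 to 0.146 CPM (counts scaled to library size), for counting error only. No skin without imiquimod was among the samples, so no value is set against untreated skin.

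The 2 IMQ+VEH libraries differed from each other by a root mean square of 0.64 in log2 CPM over 15068 genes, and 1506 genes differed more than 2-fold between them. IMQ+IDMF lay nearer to each IMQ+VEH library than these lay to each other, at 0.59 from replicate 1 and 0.56 from replicate 2. IMQ lay farthest from the rest, at 0.76 and 0.68 from the IMQ+VEH libraries and 0.69 from IMQ+IDMF. Lists of several kinds stood apart within the IMQ+VEH pair. Replicate 2 was lower than replicate 1 by a median log2 difference of -0.99 for fibroblast and matrix markers and -1.05 for endothelial markers. Smooth muscle had -0.98, Schwann and nerve -0.65, monocyte, macrophage and dendritic -0.58 and skeletal muscle markers -0.56. Replicate 2 was higher for epidermal terminal differentiation (0.57), cholesterol synthesis (0.54) and NRF2 target genes (0.47).

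The comparison of IMQ+IDMF with IMQ+VEH asked what the compound adds to the lotion on imiquimod-treated skin. No single gene passed the threshold. No list was called with an estimated correlation (adjusted p of at least 0.71), a test that rests on 1 residual degree of freedom and has little power. By direction, 16 of 23 hair follicle markers were higher in IMQ+IDMF than in both IMQ+VEH libraries. Lower than in both were 22 of 25 monocyte, macrophage and dendritic markers, 24 of 31 interferon response genes, 16 of 22 fibroblast and matrix markers, 14 of 21 stress keratins and SPRR genes and 9 of 16 neutrophil markers. By chance 1 library lies below both of 2 others for 33.3% of genes, and above both for 33.3%. By edgeR, 0 of 15068 genes were called, 306 had an unadjusted p under 0.05 where 753.4 would be expected by chance, and the smallest adjusted p was 0.267 (Gm10436, chosen after its values were seen). DESeq2 also called 0. Of the 29 lists, camera called 16 at the preset correlation, 6 higher and 10 lower, and with an estimated correlation or by fry it was 0. As a measure of how far lists move between replicates, the medians of 14 of the 29 lists lay outside the central 95% of random lists between the 2 IMQ+VEH libraries, where 1.45 would be expected. Genes of many lists thus moved together between libraries that were treated alike. Adjusted p-values from camera at the preset correlation are therefore likely too small. IMQ+IDMF had 18 such lists against the IMQ+VEH mean, and 19 against each replicate.

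Among immune lists, monocyte, macrophage and dendritic markers had a median log2 difference of -0.64 to the IMQ+VEH mean (-0.90 to replicate 1 and -0.43 to replicate 2), and 22 of 25 members were below both libraries. Camera gave an adjusted p of 2.31e-18, and adjusted p = 0.71 with an estimated correlation. The IMQ+VEH pair itself differed by -0.58 on this list. Examples were Lyz2, a lysozyme of myeloid cells (log2 fold change -1.21, SE 0.40), Ccr2, the receptor that draws monocytes into tissue (-1.15, SE 0.44), and Fcgr1, an Fc receptor (-1.18, SE 0.54). Differences to replicate 1 were larger than to replicate 2: -1.56 and -0.76 for Lyz2, -1.53 and -0.60 for Ccr2, and -1.38 and -0.89 for Fcgr1. Neutrophil markers had a median of -0.51 (-0.44 and -0.36 to the single libraries, 9 of 16 below both and 2 above both, camera adjusted p = 0.000625, and adjusted p = 0.71 with an estimated correlation), against 0.06 within the IMQ+VEH pair. Examples were Fpr2, a formyl peptide receptor (-1.58, SE 0.81), and Mmp9 (-0.67, SE 0.47). T and NK markers had a median of -0.24 (-0.44 and -0.23), with 10 of 22 below both (camera adjusted p = 0.0363, and adjusted p = 0.71 with an estimated correlation), and the T cell receptor chain genes Cd247 (-1.91, SE 0.85) and Cd3g (-1.38, SE 0.62) as examples. Mast cell markers had a median of -0.52 (-0.95 and -0.35), with 5 of 9 below both (camera adjusted p = 0.0363, and adjusted p = 0.793 with an estimated correlation). B and plasma markers (-0.25) and Langerhans markers (-0.16) were not called, with camera adjusted p of 0.181 and 0.236.

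Type I interferon response genes had a median of -0.57 (-0.64 and -0.53 to the single IMQ+VEH libraries), and 24 of 31 were below both libraries. Camera gave an adjusted p of 1.53e-09, and adjusted p = 0.71 with an estimated correlation. The median within the IMQ+VEH pair was -0.09, and against IMQ the IMQ+IDMF median was -0.0037. Examples were Rsad2, an antiviral enzyme (log2 fold change -0.85, SE 0.67), Ifi44 (-0.86, SE 0.46) and the RNA sensor gene Ddx58 (-0.44, SE 0.39). Macrophage markers were lower in the same library, as given above. The IL-1 family and IL-36 list had a median of -0.26 (-0.07 and -0.38 to the single libraries), with 8 of 15 below both (camera adjusted p = 0.0254, and adjusted p = 0.793 with an estimated correlation). The IL-23/IL-17 axis (-0.13), NF-kB target genes (-0.08) and myeloid chemokines and cytokines (0.31) were not called, with camera adjusted p of 0.405, 0.341 and 0.274. The cytokine genes had few counts: Il17a had 12 in IMQ+IDMF against 70 and 8 in IMQ+VEH (log2 fold change -1.44, SE 1.12), and Il17f had 22 against 106 and 8 (-1.10, SE 1.09). Without replicate 1 these became 0.45 for Il17a and 1.32 for Il17f. The values were 0.17 (SE 0.80) for Il23a and 0.88 (SE 0.62) for Il1b. For Il1b the log2 CPM difference was 1.49 to replicate 1 and 0.38 to replicate 2. Il22 had 3 counts in IMQ and 0 in the other 3 libraries, and was not tested.

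In the epidermal lists, stress keratins and SPRR genes, which are induced in inflamed epidermis, had a median of -0.32 (-0.33 and -0.30 to the single libraries, 0.03 within the IMQ+VEH pair), with 14 of 21 below both. Camera gave an adjusted p of 1.28e-05, and adjusted p = 0.71 with an estimated correlation. Sprr2f had a log2 fold change of -1.14 (SE 0.34) and Stfa2 of -0.50 (SE 0.28), while Krt6a and Krt16 had -0.13 (SE 0.54) and -0.02 (SE 0.65). Antimicrobial and alarmin genes had a median of -0.25 (-0.10 and -0.32), less than the -0.38 within the IMQ+VEH pair, with 9 of 19 below both (camera adjusted p = 0.000448, and adjusted p = 0.71 with an estimated correlation). Examples were S100a8 (-0.83, SE 0.60) and S100a9 (-1.06, SE 0.67), the subunits of calprotectin, and Defb3, a beta-defensin (-0.87, SE 0.36). Replicate 1 carried these values: the differences to replicates 1 and 2 were -1.26 and -0.23 for S100a8, -1.52 and -0.40 for S100a9, and -1.25 and -0.32 for Defb3. The pair itself differed by -1.03, -1.11 and -0.92 for these genes. Epidermal terminal differentiation genes were not called (median -0.02, camera adjusted p = 0.0552). Their median was 0.23 to replicate 1 and -0.40 to replicate 2, and the pair differed by 0.57. Basal keratinocyte genes had a median of 0.32 (0.37 and 0.31), with 11 of 12 above both (camera adjusted p = 1.67e-05, and adjusted p = 0.71 with an estimated correlation), including the hemidesmosome genes Col17a1 (0.50, SE 0.36) and Itgb4 (0.34, SE 0.26). Cell cycle genes had a median of 0.27 (0.12 and 0.34), with 19 of 26 above both (camera adjusted p = 1.37e-05, and adjusted p = 0.71 with an estimated correlation), including Mcm2 (0.77, SE 0.30) and Mcm5 (0.64, SE 0.30) of the replicative helicase. These 2 were among the 6 members that also lay above IMQ. The list median to IMQ was -0.32, and the IMQ+VEH pair differed by -0.20. Ccnb1 (0.08, SE 0.29) and Top2a (0.10, SE 0.27) of this list lay slightly below replicate 1 (-0.02 and -0.08). The hair follicle markers described with the other tissue lists were also higher in this library.

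Dimethyl fumarate is known as an activator of NRF2, the transcription factor of the antioxidant response. NRF2 target genes had a median of 0.17 in IMQ+IDMF against IMQ+VEH, with 11 of 39 above both libraries and 4 below both (camera adjusted p = 0.00201, and adjusted p = 0.793 with an estimated correlation). The direction depended on the IMQ+VEH library: the median was 0.41 to replicate 1 and -0.08 to replicate 2, and the 2 IMQ+VEH libraries differed by 0.47. Nqo1, a quinone reductase and common readout of NRF2, had 966 counts in IMQ+IDMF against 395 and 930 in IMQ+VEH and 734 in IMQ (log2 fold change 0.54, SE 0.49, and -0.07 without IMQ+VEH replicate 1). Values for Gclc, which makes glutathione precursors, Hmox1, a heme oxygenase, and Srxn1, a sulfiredoxin, were 0.26 (SE 0.30), -0.23 (SE 0.27) and 0.04 (SE 0.33). Differences to replicates 1 and 2 were 0.48 and 0.06 for Gclc, -0.10 and -0.35 for Hmox1, and 0.53 and -0.32 for Srxn1. Tkt (0.54, SE 0.30) and Gstm1 (0.43, SE 0.30) were among the members above both libraries. They lay above by 0.48 and 0.61 for Tkt, and by 0.74 and 0.17 for Gstm1. Hcar2, a receptor for monomethyl fumarate, had -0.05 (SE 0.28). AhR target genes (-0.10), cholesterol synthesis (-0.07), heat shock and unfolded protein response (0.11) and immediate early genes (0.12) were not called, with camera adjusted p of 0.561, 0.333, 0.181 and 0.0705.

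Among the tissue lists, hair follicle markers had a median of 0.91 (0.97 and 0.96 to the single IMQ+VEH libraries, 0.12 within the pair), with 16 of 23 above both. Camera gave an adjusted p of 5.94e-19, and adjusted p = 0.71 with an estimated correlation. Adjusted over all genes 0 members passed, and adjusted over the list alone 3 did. These 3, chosen after their values were seen, are hair shaft and inner root sheath keratins: Krt35 had 72 counts in IMQ+IDMF against 4 and 0 in IMQ+VEH, Krt85 had 26 against 0 and 0, and Krt71 had 26 against 8 and 3. IMQ alone had 193, 36 and 452 counts of these genes. Hoxc13, a regulator of hair keratins, had a log2 fold change of 1.36 (SE 0.49). Fibroblast and matrix markers had a median of -0.77, which was -1.33 to replicate 1 and -0.33 to replicate 2, with 16 of 22 below both (camera adjusted p = 3.36e-20, and adjusted p = 0.71 with an estimated correlation). The IMQ+VEH pair itself differed by more on this list (-0.99). Fbn1, which codes for fibrillin, had -1.45 (SE 0.51), with -2.04 to replicate 1 and -0.40 to replicate 2. Smooth muscle (0.35), skeletal muscle (0.12) and Schwann and nerve markers (-0.48) were called by camera (adjusted p 0.0327, 0.0363 and 0.026), and adjusted p = 0.793 with an estimated correlation for each. The Schwann and nerve median was -0.69 to replicate 1 and -0.05 to replicate 2, and the pair itself differed by -0.65. The muscle lists had no constant direction: smooth muscle had -0.02 to replicate 1 and 0.93 to replicate 2, and skeletal muscle -0.03 and 0.42. Endothelial (-0.06), adipocyte (0.03) and sebaceous gland markers (0.12) were not called, with camera adjusted p of 0.923, 0.425 and 0.0915. The direction of each depended on the IMQ+VEH library. To replicates 1 and 2 the endothelial median was -0.49 and 0.53, the adipocyte median -0.23 and 0.16, and the sebaceous gland median 0.37 and -0.07. For the endothelial list the mean (0.02) and the test pointed higher while the median was below 0. Of the 16 called lists, 13 lay on the same side of both IMQ+VEH libraries, and 10 of these also had a median larger than the difference within the pair. That difference is a weak measure of replicate variation, because it can be near 0 while members differ. The neutrophil list had 0.06 within the pair, while its members S100a8 and S100a9 had -1.03 and -1.11.

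**Figure D1:**
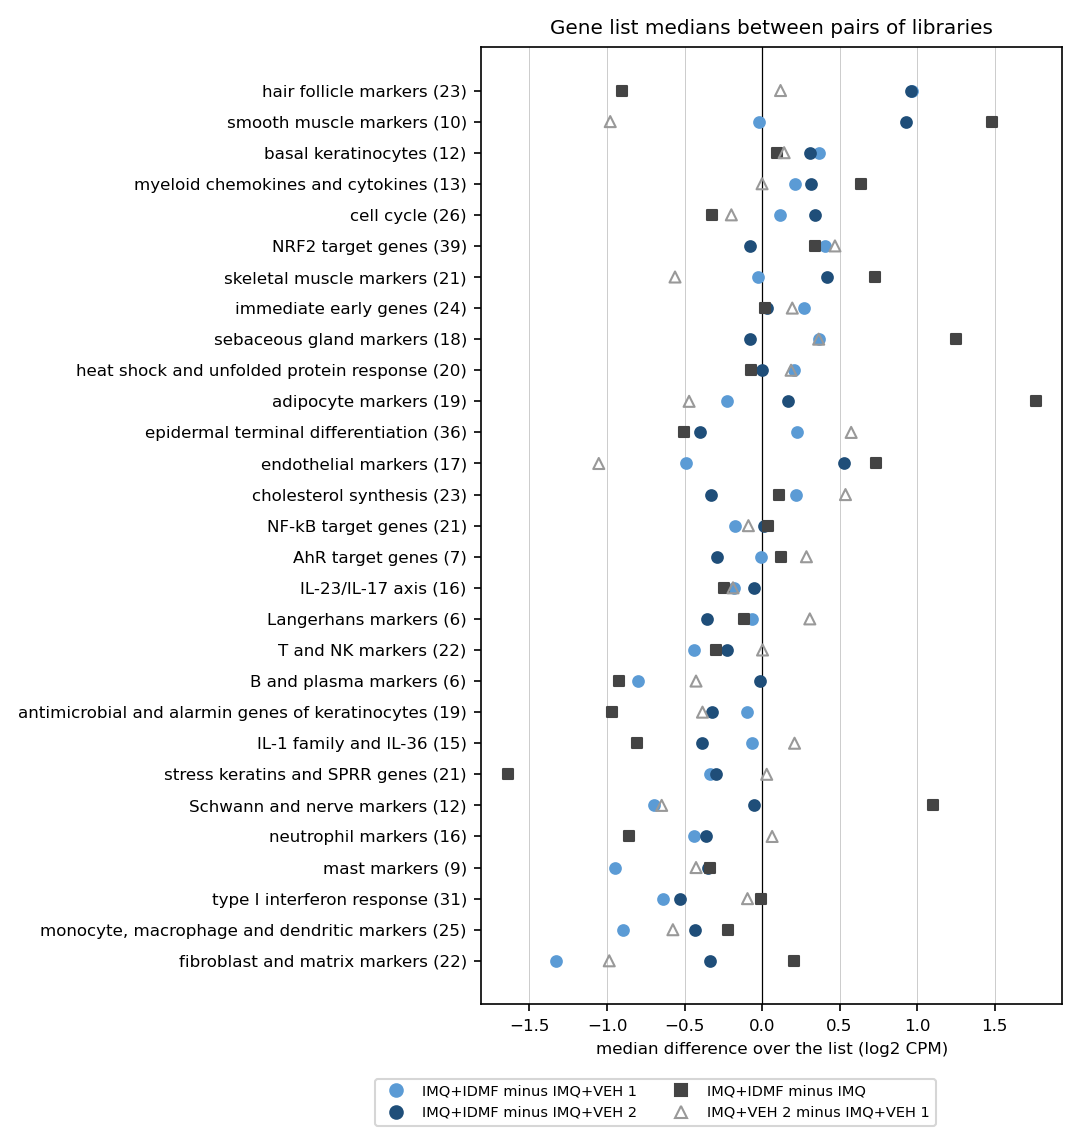
Median log2 CPM difference over each list between pairs of libraries (x axis), with the number of tested genes per list in brackets. Hair follicle markers lie at 0.97 and 0.96 above the IMQ+VEH libraries and at -0.90 to IMQ, and for many lists the 2 IMQ+VEH libraries (open triangles) lie as far apart as IMQ+IDMF from either.

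The genes for which IMQ+IDMF lay farthest above the 3 other libraries included Per2 (log2 fold change to IMQ+VEH 0.99, SE 0.45), Ciart (1.20, SE 0.45) and Dbp (0.88, SE 0.28), a core repressor, a further repressor and an output transcription factor of the circadian clock. Per2 lies on chromosome 1 (91415982 to 91459324, GRCm38), Ciart on chromosome 3 (95878503 to 95882251) and Dbp on chromosome 7 (45705088 to 45710203), where its exons overlap those of Sphk2 on the other strand. The rest were Myog, a muscle transcription factor (0.92, SE 0.63), Gins2 of the replication fork (0.85, SE 0.39), Apex2, a DNA repair nuclease (0.74, SE 0.45), Cdk18 (0.79, SE 0.56), Piwil2 (0.84, SE 0.54), Lrrc15 (1.08, SE 0.66), Zfp13 (0.91, SE 0.59), Tmem220 (0.80, SE 0.50) and Erdr1 (1.37, SE 0.41). Erdr1 had 2663 and 736 counts in the IMQ+VEH pair. The genes farthest below included Itgal, the alpha chain of the integrin LFA-1 (-1.85, SE 0.61), Cd3g of the T cell receptor complex (-1.38, SE 0.62), Cd200r1, an inhibitory receptor of myeloid cells (-1.94, SE 0.71), Tlr1 (-1.85, SE 0.70), Gpr34 (-2.09, SE 0.73), P2ry6, a nucleotide receptor (-1.90, SE 0.49), Arhgap15 (-1.79, SE 0.76) and Snx20 (-1.88, SE 0.71). The others were Defb4, a beta-defensin (-1.75, SE 0.56; chromosome 8, 19198706 to 19201545), Mrgprg (-2.66, SE 0.74), Kcnip3 (-1.94, SE 0.66) and Ddias (-1.16, SE 0.51). None of the 24 passed the threshold (adjusted p of 1 for each). IMQ+IDMF was above all 3 others for 18.7% and below all 3 for 18.4% of 12430 genes, where chance gives 25% each.

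**Figure D2:**
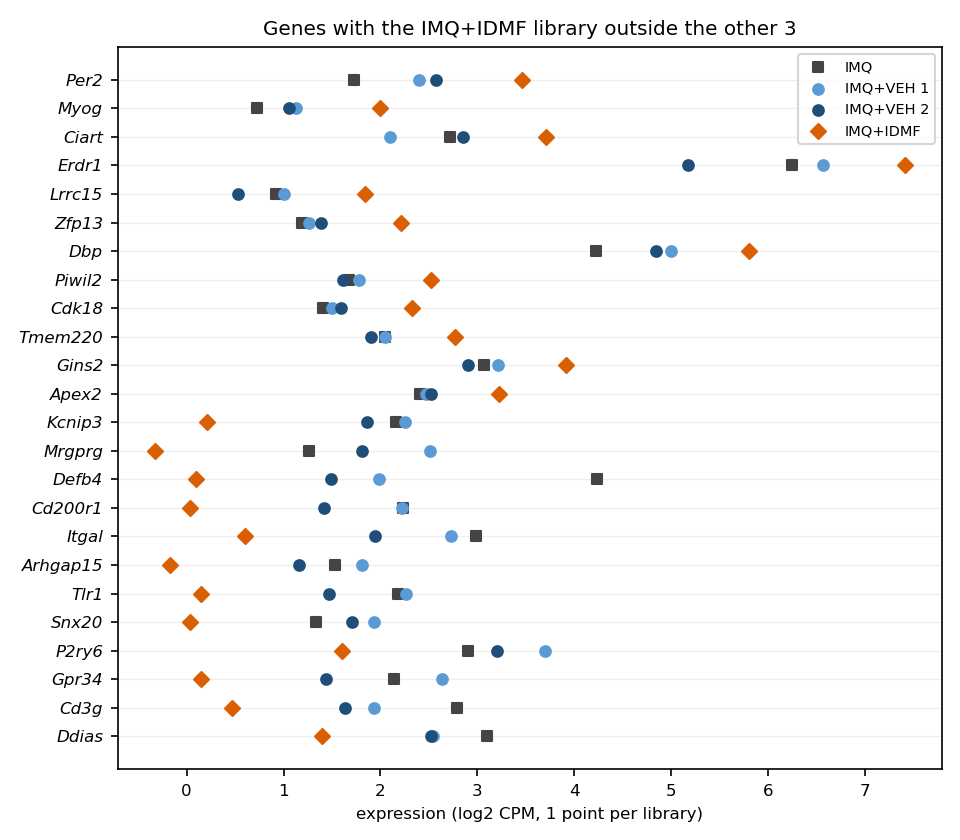
Expression of the 24 named genes in each library (log2 CPM, 1 point per library). IMQ+IDMF lies above the other 3 libraries for the first 12 genes and below them for the other 12, for Per2 by 1.07 and 0.90 above the IMQ+VEH libraries and 1.74 above IMQ.

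The test rested on the spread of 1 pair of libraries, and 0 calls does not show that the groups were alike. Without a filter on low counts edgeR gave every gene the common trend of spread, with infinite prior degrees of freedom, and called 16 genes, 11 higher and 5 lower, all of them among the 15068 tested here.

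The comparison of IMQ+VEH with IMQ asked what the lotion without the compound does to imiquimod-treated skin. By direction, 19 of 21 stress keratins and SPRR genes, 21 of 23 hair follicle markers and 11 of 19 antimicrobial and alarmin genes were below IMQ in both IMQ+VEH libraries, and 18 of 19 adipocyte, 17 of 18 sebaceous gland and 11 of 12 Schwann and nerve markers were above. Of the 12430 genes eligible for naming, 36.1% were below and 32.7% above IMQ in both libraries. No list was called with an estimated correlation (adjusted p of at least 0.566), a test with little power at 1 residual degree of freedom. EdgeR called 100 of 15068 genes, 51 higher and 49 lower, and 1327 genes had an unadjusted p under 0.05 where 753.4 would be expected. The largest drops by the naming rule were those of Tmprss11a, an epithelial serine protease (log2 fold change -4.51, SE 0.46, adjusted p = 0.000859), Lce3b (-3.76, SE 0.27, adjusted p = 0.000122; chromosome 3, 92932979 to 92934097), S100a7a (-3.88, SE 0.56), Sprr2f (-3.65, SE 0.30; chromosome 3, 92365187 to 92366442), Tmprss11b (-3.62, SE 0.55) and the inner root sheath keratin Krt73 (-3.75, SE 0.62). Among the largest rises were those of Adcyap1r1, the receptor for the neuropeptide PACAP (3.68, SE 0.59), Rbp4, a retinol carrier (3.01, SE 0.43), Gsta3, a glutathione transferase (7.99-fold, SE 0.38 on the log2 scale), Timp4 (2.95, SE 0.43) and Cyp2f2 (2.77, SE 0.34). The adjusted p of these 11 genes lay between 0.000122 and 0.0173, and both IMQ+VEH libraries lay on the same side of IMQ for each. Exons of Timp4 overlap those of Syn2 on the other strand.

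**Figure D3:**
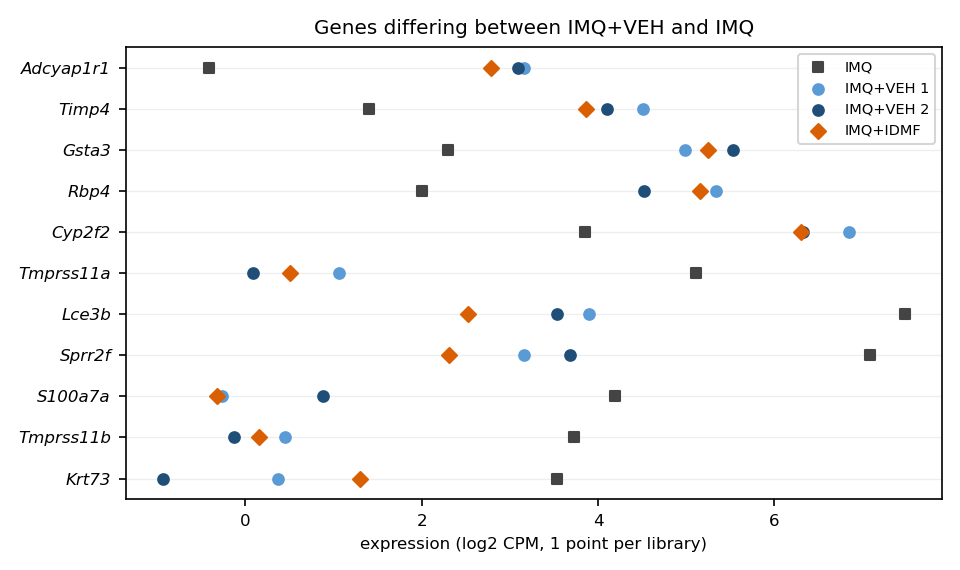
Expression of 11 named genes in each library (log2 CPM, 1 point per library). Both IMQ+VEH libraries lie apart from IMQ for each gene, as the rule that named them asks, for Lce3b by -3.59 and -3.94.

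Stress keratins and SPRR genes had a median of -1.38 (-1.55 and -1.36 for the single IMQ+VEH libraries), with 19 of 21 below IMQ in both. Of these, 6 fell when adjusted over all genes and 12 adjusted over the list alone. Camera gave an adjusted p of 1.44e-42, and adjusted p = 0.566 with an estimated correlation. Sprr2i (-2.82, SE 0.26) and Sprr2e (-2.44, SE 0.26) code for proteins of the cornified envelope, and Stfa2 (-1.94, SE 0.26) for a cysteine protease inhibitor. Krt6a (-1.88, SE 0.51) passed over the list alone, and Krt16 (-1.06, SE 0.63) did not pass. Antimicrobial and alarmin genes had a median of -0.90, with 11 of 19 below IMQ in both libraries and 4 above (camera adjusted p = 4.08e-11, and adjusted p = 0.566 with an estimated correlation). The 5 that fell over all genes were Defb3 (-2.77, SE 0.33), Defb4 (-2.49, SE 0.45), Saa3 (-2.35, SE 0.30), S100a7a and, chosen after its value was seen, Wfdc12 (-2.01, SE 0.30). Adjusted over the list alone, 6 were lower and 1 higher, with Saa1 and Lrg1 added after their values were seen. S100a8 had -1.42 (SE 0.56) and S100a9 -1.37 (SE 0.61). Epidermal terminal differentiation genes had a median of -0.42, which was -0.83 in replicate 1 and -0.17 in replicate 2 (camera adjusted p = 9.84e-19, and adjusted p = 0.683 with an estimated correlation). The 4 that fell over all genes were late cornified envelope genes of one family, Lce3b, Lce3a (-3.28, SE 0.31), Lce3f (-2.11, SE 0.29) and Lce3c (-2.08, SE 0.31), and 6 passed adjusted over the list alone. Basal keratinocyte genes had a median of -0.14 (-0.25 and -0.13; camera adjusted p = 0.0468, and adjusted p = 0.705 with an estimated correlation). All 26 cell cycle genes were below IMQ in both libraries, with a median of -0.62 and no member past the threshold (camera adjusted p = 2.5e-10, and adjusted p = 0.566 with an estimated correlation).

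Hair follicle markers had a median of -1.92 (-1.69 and -2.11), with 21 of 23 below IMQ in both libraries (camera adjusted p = 1.15e-28, and adjusted p = 0.566 with an estimated correlation). The 5 that fell over all genes were Krt73, Krt71 (452 counts in IMQ against 8 and 3), Krt35 (193 against 4 and 0), Krt25 (375 against 4 and 10) and, chosen after its value was seen, Tchh (-2.77, SE 0.40), and 12 passed adjusted over the list alone. Adipocyte markers had a median of 1.70 (1.92 and 1.48), with 18 of 19 above IMQ in both. Of these, 7 rose over all genes and 17 adjusted over the list alone, among them the lipid droplet genes Cidec (2.62, SE 0.39) and Plin1 (2.49, SE 0.41) and the adipokine gene Retn (2.02, SE 0.29). Camera gave an adjusted p of 2.14e-35, and adjusted p = 0.566 with an estimated correlation. Schwann and nerve markers had a median of 1.26 (1.51 and 0.99; camera adjusted p = 2.5e-10, and adjusted p = 0.683 with an estimated correlation), and the myelin gene Pmp22 rose over all genes (2.09, SE 0.42), with 7 members past the threshold over the list alone. Sebaceous gland markers had a median of 0.95 (0.82 and 1.14; camera adjusted p = 5.59e-13, and adjusted p = 0.566 with an estimated correlation), with 1 gene, the wax and lipid synthesis gene Dgat2l6 (2.02, SE 0.33), over all genes and 8 over the list alone. Fibroblast and matrix markers had 1.00 (1.39 and 0.45), with 0 genes over all genes and 9 over the list alone (camera adjusted p = 8.15e-14, and adjusted p = 0.705 with an estimated correlation). Smooth muscle markers had 1.30 (1.87 and 0.76), with 0 and 5 (adjusted p 5.58e-08, and adjusted p = 0.683 with an estimated correlation). Skeletal muscle (0.62, of which 0.82 in replicate 1 and 0.31 in replicate 2) and endothelial markers (0.75, of which 1.19 in replicate 1 and 0.12 in replicate 2) were also called (adjusted p 1.63e-06 and 0.000235, and adjusted p = 0.705 and 0.788 with an estimated correlation).

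Type I interferon response genes had a median of 0.62 (0.67 and 0.57), with 26 of 31 above IMQ in both libraries and 0 past the threshold (camera adjusted p = 1e-04, and adjusted p = 0.566 with an estimated correlation). Examples were Isg15 (1.34, SE 0.49) and Irf7 (1.01, SE 0.30). Monocyte, macrophage and dendritic markers had 0.25 (camera adjusted p = 0.0455, and adjusted p = 0.788 with an estimated correlation). Neutrophil markers had -0.70 (-0.72 and -0.63), with 1 gene, Stfa2l1 (-1.81, SE 0.38), over the list alone (camera adjusted p = 0.000145, and adjusted p = 0.566 with an estimated correlation). The IL-1 family and IL-36 list had -0.30 (-0.51 and -0.16; camera adjusted p = 0.00118, and adjusted p = 0.705 with an estimated correlation), with Il1b (-2.59, SE 0.59, 245 counts against 28 and 46) and Il33 (-1.05, SE 0.27) past the threshold over the list alone. NRF2 target genes had 0.08, which was -0.11 in replicate 1 and 0.40 in replicate 2 (camera adjusted p = 0.01, and adjusted p = 0.819 with an estimated correlation), with Gsta3 over all genes and, with it, Aox1 over the list alone. Of the myeloid chemokines and cytokines, Cxcl2, a neutrophil chemokine chosen after its value was seen, had 87 counts in IMQ and 0 in both IMQ+VEH libraries (adjusted p = 0.0189). That list was not called (camera adjusted p = 0.575), and its median (0.42) differed in sign from its mean (-0.31) and its test. The IL-23/IL-17 axis (-0.21) was not called (adjusted p 0.447), and 1 gene, Ccl20, chosen after its value was seen, was higher over the list alone (1.99, SE 0.46). Also not called were NF-kB target genes (0.12), AhR target genes (0.30), cholesterol synthesis (0.12), heat shock and unfolded protein response (-0.04), immediate early genes (-0.05), Langerhans (0.04), T and NK (0.02), B and plasma (-0.66) and mast cell markers (0.29). The heat shock and immediate early medians turned to 0.03 and 0.02 with total counts in place of TMM. For immediate early genes the mean (0.11) was above 0 while the median and the test pointed lower, and for T and NK markers the test pointed lower at a median and mean of 0.02.

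Camera called 18 of the 29 lists in this comparison, 10 higher and 8 lower, and with an estimated correlation or by fry it was 0. DESeq2 called 202 genes, 99 of them among the 100, and edgeR without a filter on low counts called 424. IMQ was a single library, so a difference between its skin and the others cannot be separated from the lotion.

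IMQ+IDMF against IMQ set 1 library against 1, so no p-value is given. The same IMQ library also served as the reference for IMQ+VEH, so likeness of the 2 comparisons is not independent evidence. The lowest median log2 differences were -1.64 for stress keratins and SPRR genes, -0.97 for antimicrobial and alarmin genes, -0.92 for the 6 B and plasma markers, -0.90 for hair follicle markers, -0.86 for neutrophil markers and -0.81 for the IL-1 family and IL-36. The highest were 1.76 for adipocyte, 1.48 for smooth muscle, 1.25 for sebaceous gland and 1.10 for Schwann and nerve markers. Lce3b had a log2 CPM difference of -4.95, Sprr2f of -4.77 and Defb4 of -4.14. The medians of 18 of the 29 lists lay outside the central 95% of random lists, 9 above and 9 below, where 1.45 would be expected. Between the 2 IMQ+VEH libraries, which were treated alike, it was 14.

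Against the 3 other libraries as 1 group, IMQ+IDMF gave 0 of 15068 genes by edgeR, with 168 at an unadjusted p under 0.05 where 753.4 would be expected. DESeq2 called 1 gene, the predicted gene Gm10436, chosen after its values were seen, with 122 counts in IMQ+IDMF against 1 in IMQ and 0 and 1 in IMQ+VEH.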

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

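The fits on only 3 libraries, the FPKM values and the other settings for list medians and named genes of IMQ+VEH against IMQ were chosen after the data were seen. The count of 0 genes between IMQ+IDMF and IMQ+VEH was also 0 with the other scalings, a mean count of at least 50, the robust fit, the fit without muscle, adipocyte and hair follicle genes, IMQ and IMQ+VEH as 1 group, only 3 libraries, and DESeq2. It was 16 without a filter on low counts. There edgeR's prior degrees of freedom went from 11.2 to infinity, so no gene kept a spread of its own, and all 16 were tested in both settings. For IMQ+VEH against IMQ the count of 100 went to 424 without the filter and to 202 by DESeq2, and both raised the share of calls that were higher from 51.0% to 73.1% and 69.3%. The cause of the DESeq2 value was not tested. Other settings stayed within 1.5 times of 100, and only 3 libraries gave 100, of which 97 were shared. Against all 3 other libraries DESeq2 gave 1 gene and every edgeR setting 0, including those without 1 library in turn. The calls of lists went from 16 and 18 to 0 with an estimated correlation and to 0 by fry, in both comparisons. Both alternatives rest on 1 residual degree of freedom, so the 0 says little for or against the lists.

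Leaving out 1 IMQ+VEH library turned 4 medians of called lists. NRF2 target genes against IMQ+VEH had -0.0769 without replicate 1 and 0.41 without replicate 2, and for IMQ+VEH against IMQ 0.40 and -0.109. Smooth muscle markers had 0.93 and -0.0208, and skeletal muscle markers 0.42 and -0.0263, in IMQ+IDMF against IMQ+VEH. The cause was not tested. DESeq2 size factors and total counts changed the sign of no list median in IMQ+IDMF against IMQ+VEH. With log2(FPKM + 1), 5 of 29 medians moved by at least the standard deviation of the IMQ+VEH pair and 1 changed sign (adipocyte, not called there), and for IMQ+VEH against IMQ 11 moved and 2 changed sign (heat shock and immediate early, as with total counts, neither called there). Total counts in place of TMM moved the median of all genes between the 2 IMQ+VEH libraries to -0.15. With 1 residual degree of freedom, 2-fold changes were mostly out of reach in the simulated data (22.7% found).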

Other observations

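The hedgehog, stem region and outer root sheath, and clock gene groups, the patterns and all tests weighed here were chosen after the values were seen, while the stress keratin and SPRR, sebaceous gland, hair follicle, skeletal muscle, smooth muscle, Schwann and nerve, basal keratinocyte, adipocyte, fibroblast and endothelial lists were fixed earlier. Of the hedgehog pathway, which acts in hair follicle growth, some genes lay higher in IMQ+IDMF than in IMQ+VEH, and none passed the threshold. Shh, the ligand, had 67 counts in IMQ+IDMF against 2 and 4 in IMQ+VEH and 62 in IMQ. Its target Gli1 had a log2 fold change of 1.69 (SE 0.35), while Ptch1, which was lower than in replicate 1, had 0.01 (SE 0.43) and Smo 0.09 (SE 0.26). The median of 7 hedgehog genes was 0.69 and 1.17 above the IMQ+VEH libraries and -0.02 to IMQ. Exons of Shh and Gli1 overlap those of other genes on the opposite strand.

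Among clock genes, those with the phase of Per2 and Dbp lay higher in IMQ+IDMF than in IMQ+VEH: Tef (0.48, SE 0.27), Hlf (0.77, SE 0.37), Per1 (0.47, SE 0.28) and Per3 (0.29, SE 0.28). The others of that phase were Bhlhe41 (0.37, SE 0.34), Nr1d2 (0.25, SE 0.26) and Nr1d1 (0.11, SE 0.27). Those of the opposite phase lay lower: Arntl (-0.50, SE 0.32), Nfil3 (-0.60, SE 0.39), Clock (-0.26, SE 0.28) and Npas2 (-0.44, SE 0.69). None passed the threshold. Against IMQ, Hlf (-0.14) and Npas2 (0.22) went the other way. When each library in turn was set against the 3 others by edgeR, 55 genes were called for IMQ, 35 of them higher, and 0 for each IMQ+VEH library and for IMQ+IDMF, with 1867, 1068, 295 and 168 genes at an unadjusted p under 0.05 for IMQ, IMQ+VEH replicates 1 and 2, and IMQ+IDMF.

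The first pattern is that most hair follicle markers (16 of 23) were higher in IMQ+IDMF than in both IMQ+VEH libraries. More whole follicles with their glands in the IMQ+IDMF piece would raise sebaceous gland markers by a like amount. That list differed by at most 0.37 (-0.07 to the other IMQ+VEH library), and 9 stem region and outer root sheath genes by at most 0.30. Hair follicle markers differed by 0.97 and 0.96, which argues against it as the whole cause. In IMQ+VEH against IMQ the sebaceous gland and hair follicle medians moved in opposite directions (0.95 and -1.92). The sebaceous gland list is therefore an uncertain measure of follicles here. Variation between skins that needs no IDMF, such as the stage of hair growth, is a candidate explanation: the hair follicle median of IMQ+IDMF lay at -0.90 to IMQ, so a library without IDMF reached a higher level. IMQ also received no lotion, so its level cannot separate variation between skins from an effect of the lotion. The IMQ+VEH libraries, which were treated alike, differed by only 0.12 on this list. An effect of IDMF on follicles stays open and untested beyond this, with 1 library.

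The second pattern is that Per2, Ciart and Dbp were higher in IMQ+IDMF than in the 3 others. More skeletal muscle in that piece is argued against as the cause of the difference to IMQ+VEH replicate 1. There skeletal muscle markers had a median of -0.03, against 1.07 for Per2, Ciart and Dbp. To replicate 2 and IMQ the muscle medians were 0.42 and 0.73, against 0.90 and 1.58. More muscle as part of the cause stays open for these libraries. The smallest excess, 0.47 to replicate 2, lay within the 0.62 by which the excess varied between the IMQ+VEH libraries. Collection at another clock time may account for the pattern: over the other clock genes, the median of the same phase minus that of the opposite phase was at least 0.76 above each of the 3 libraries, against 0.15 between the IMQ+VEH libraries. Clock times of collection were not used here, and an effect of IDMF on the clock would give the same values, so it stays open.

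The third pattern is that most stress keratins and SPRR genes (19 of 21) were lower, and most fat genes (18 of 19) higher, in both IMQ+VEH libraries than in IMQ. An equal loss of all epidermal layers as the whole cause of the lower SPRR genes is argued against by the basal keratinocyte median. It was -0.14 (-0.25 and -0.13), against -1.55 and -1.36 for stress keratins and SPRR genes. In the basal list 6 of 12 genes were below IMQ in both libraries and 1 above, and Krt14 had -1.10 (SE 0.73). Basal genes cannot show a loss of upper layers alone, so that stays open. Less epidermis as the whole cause of the higher fat genes would raise other types outside the epidermis alike. However, adipocyte markers exceeded 4 of 5 such lists in both libraries by more than the excess varied between them. This was clearest for skeletal muscle (1.10 and 1.17) and Schwann and nerve markers (0.41 and 0.49). It was narrow for fibroblast markers (smaller excess 0.53, variation 0.49) and endothelial markers (0.73 and 0.62). Smooth muscle was exceeded by only 0.06 and 0.72, so less epidermis as part of the cause stays open. More subcutaneous fat in the pieces and an effect of the lotion on fat genes cannot be told apart: 94.7% of adipocyte genes were above IMQ in both libraries, which both would give. The effect of the lotion on inflammation stays open for the SPRR genes, and all these values rest on 1 IMQ library.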
